A study of Mus musculus with 10 samples.

How the data were processed

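RNA from gonadal white adipose tissue of 10 female C57BL/6 mice was sequenced, per the labels. The 5 KO and 5 WT libraries were compared, each named by its group and the animal number in its title. The animal numbers are not shared between the groups, so no pairing was used. The labels give no batch, litter or sequencing date. They describe tamoxifen for the mice with the inducible adipose deletion of Med19, and whether the control mice received it is not given in the sources used here.

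The values analysed were RPKM (reads scaled to gene length and to library size), which the authors deposited as one table of genes and one of transcripts. The labels name polyA RNA as the molecule and standard Illumina library protocols. The submitters' processing notes name bcl2fastq, STAR, Subread and featureCounts. The genome build, the annotation release, the filters and the program that divided reads among transcripts are not given in the sources used here, so no coordinates are printed. The file names are the only source for the unit of the transcript table, and its values are described as RPKM on that basis. All per-sample columns were used.

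Rows repeated for one identifier held the same values and were used once, which left 40503 genes from 40770 rows and 84046 transcripts from 84752 rows. Within a gene, RPKM values of the libraries were whole multiples of a common step, and whole reads were found for 100% of the 25122 genes above 0 in at least 3 libraries, with a tolerance of 0.001 reads. The recovered totals over these genes gave 14441275 to 20179236 reads assigned to genes per library. The library size behind the RPKM values was 1.0012 to 1.0014 times the recovered reads in each of the 10 libraries, so no further scaling between libraries was seen in the deposited values. That size was worked out with exon lengths of GENCODE M21. These equalled the lengths behind the values for 16148 of the 25094 recovered genes found in that release. On a simulated table of 3000 genes, reads were found for 98.2% of genes, and 99.9% of those were exact. Recovered reads served for depth, for shares of reads and for an added voom fit.

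Genes with an RPKM of at least 0.5 in at least 5 of the 10 libraries were tested, which kept 17038 genes. Log2 of RPKM plus a pseudocount of 0.5 was fitted with limma 3.58.1 in R 4.3.3, with eBayes (trend and robust, with statmod 1.5.0), 2-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. A fold change is on the log2(RPKM + 0.5) scale and understates the change of low genes, and its SE is limma's moderated SE. All adjusted p-values of genes and transcripts are from limma. Transcripts were fitted in the same way, with 44475 tested. Med19 was compared by a 2-sided exact permutation test over 252 assignments of 5 and 5 libraries, whose smallest p is 0.0079.

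Gene lists, 38 in all, were fixed before the data were examined, and 37 had at least 5 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry were alternatives. Counts of members called over all genes and adjusted over the list alone are given. The genes named were set by a rule fixed before the data were examined. It took Med19, then the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose mean reached 2 RPKM in the higher group. Predicted or clone-named genes, pseudogenes and immunoglobulin or T cell receptor segments were left out of that part. Up to 4 called members per list with the largest change followed, and up to 2 of the most abundant members as values where fewer than 2 were called. Adipoq, Pparg, Slc7a10, Nrg4, Apoc1, Dpt, Srgn, S100a8 and Igkv14-111 were named after their values were seen.

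The fit was tested on simulated reads drawn for the real genes and library sizes, with 200 genes changed. Of 17040 simulated genes tested, 175 were called, and 12 of them (6.86%) were unchanged genes. The changed genes were drawn at random with rises and falls near balance, so this rate does not cover calls that come from a shift of all genes. The fit recovered 64.2% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 95.4% of those changed 4-fold, and called 0 genes in a simulation with no change. Simulated genes of similar abundance were given the same variability between libraries. These rates therefore do not cover genes that vary more or less than others of their abundance. Of 40 simulated lists with no change, camera called 1. The simulated genes were drawn independently of each other, so this does not cover lists whose members vary together. Other groupings of the real libraries gave a median of 11 called lists.

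Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter, a filter at 1 RPKM, median-ratio scaling, quantile normalization, eBayes without trend or robust, array weights, and leaving out each library. Subsets of animals by number were also fixed. The subset numbered under 20 left out WT 86 and WT 89, and the subset with 1-digit numbers also left out KO 17 and WT 19. The groups were therefore unequal in size in these subsets. No KO animal had a number above 20, and the labels do not say what the numbers stand for. With 1 library left out the filter asked for 4 libraries, as with 8 libraries, and with 6 it asked for 3. A member's call is described as kept throughout where it held, in the same direction, in each of the 10 runs that left out 1 library and under median-ratio scaling and quantile normalization. Voom on recovered reads, protein-coding genes rescaled to their own reads, and median-ratio scaling without KO 4 were added after the data were seen. Figures were drawn with matplotlib 3.10.9, and read recovery used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

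No replicate pair looked like 1 library deposited under 2 names. The chi-square per gene between the recovered reads of 2 libraries of a group ranged from 14.4 to 82.1 over 20 pairs, where sampling noise alone gives about 1.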

Results

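The study asked how gene expression in gonadal white adipose tissue, the fat depot beside the ovaries and uterus, changed in mice with an adipose-specific, tamoxifen-inducible knockout of Med19. Med19 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. The animals were 12 weeks old. The labels describe tamoxifen at 100 mg/kg for 5 days, with tissue taken 14 days later, for the knockout mice, and do not say whether the controls received it. RNA-seq libraries came from 5 KO and 5 WT animals. The reads assigned to genes, as recovered from the RPKM values, numbered 15179210 in KO 1, 20179236 in KO 4, 17899943 in KO 7, 15307571 in KO 8 and 17356541 in KO 17. In the WT libraries they numbered 15939942 in WT 2, 14657477 in WT 9, 16186227 in WT 19, 14441275 in WT 86 and 14928277 in WT 89.

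No difference in Med19 RNA (ENSMUSG00000027080) was detected between the groups. It was 6.79 ± 0.85 RPKM in the KO libraries and 6.70 ± 0.89 RPKM in the WT libraries (mean ± SD, n = 5 each; exact permutation p = 0.881). Single libraries ranged from 5.58 to 7.99 RPKM in the KO group and from 5.62 to 7.64 RPKM in the WT group. The 95% interval of the KO to WT ratio from limma ran from 0.862 to 1.19. The protein-coding transcript ENSMUST00000102645 was at 6.45 ± 0.48 RPKM in KO and 6.60 ± 1.02 RPKM in WT (exact permutation p = 0.786). The noncoding transcript ENSMUST00000141595 was at 0.284 ± 0.443 and 0.905 ± 0.906 RPKM (exact permutation p = 0.286). The level of the targeted gene therefore did not check the group labels, and the libraries are called KO-labelled from here on. Every direction below rests on those labels.

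Genes of fat storage and of the adipocyte state were among the largest differences and were lower in the KO-labelled libraries. Scd1, which encodes stearoyl-CoA desaturase, was at 214 ± 68 RPKM in the KO-labelled libraries against 2472 ± 672 RPKM in WT (SD, n = 5 each), and its log2 value fell by 3.54 (SE 0.22, adjusted p = 1.64e-05). Pck1, the cytosolic enzyme of glyceroneogenesis, fell by 3.12 (SE 0.21) from 218 ± 65 to 24.1 ± 5.2 RPKM. The adipokine gene Retn fell by 2.37, the beta-3 adrenergic receptor gene Adrb3 by 2.92, and the fatty acid synthase gene Fasn by 2.25 on the log2 scale. The other genes among the 10 largest falls were Tmem45b (log2 change -4.03), Nnat (-3.13), Rasd1 (-2.60), Oxtr (-2.31) and Cyp2e1 (-2.28). Adjusted p for these 10 genes ran from 6.22e-06 (Oxtr) to 6.51e-04 (Adrb3).

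**Figure D1:**
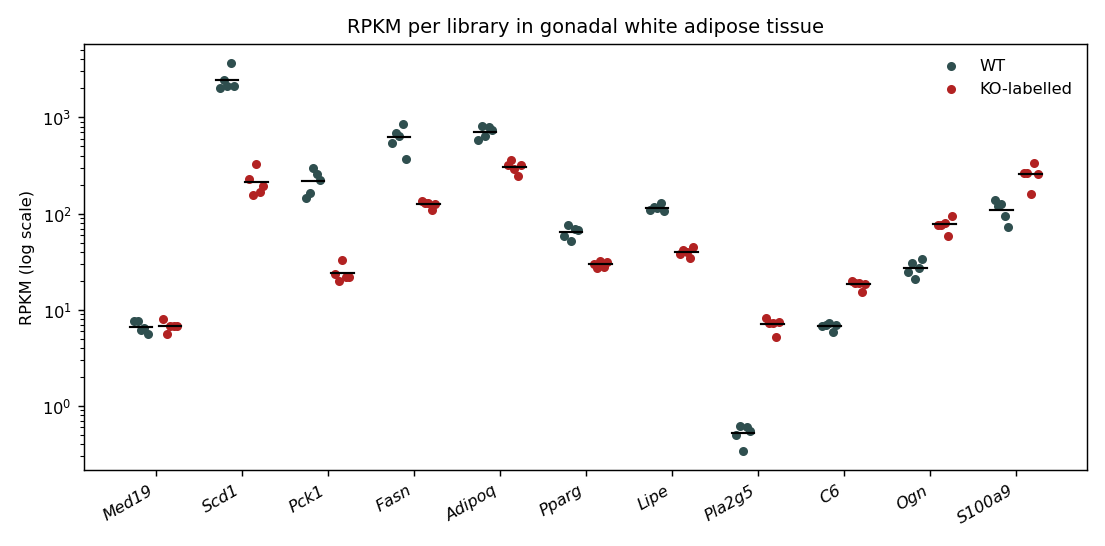
RPKM (log scale) of 11 named genes in each of the 5 WT and 5 KO-labelled libraries, with points for libraries and black lines for group means. Med19 overlaps between the groups, and the 5 KO-labelled libraries lie below all WT libraries for Scd1, Pck1, Fasn, Adipoq, Pparg and Lipe and above them for Pla2g5, C6, Ogn and S100a9.

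The largest rise was that of Pla2g5, a secreted phospholipase A2 gene, from 0.523 ± 0.110 RPKM in WT to 7.12 ± 1.12 RPKM (log2 change 2.89, SE 0.12, adjusted p = 1.71e-06). Its WT level was close to the pseudocount, so this change is an understatement. The other large rises, with log2 changes in brackets, included Kng2 (kininogen, 1.57), Itih4 (1.49), Ogn (osteoglycin, 1.48), Pon1 (paraoxonase, 1.39) and C6 (a terminal complement component, 1.38). C6 rose from 6.78 ± 0.56 to 18.4 ± 1.7 RPKM, and Ogn from 27.5 ± 5.0 to 77.3 ± 12.9 RPKM. Plppr4 (1.64), Wisp2 (1.58), Folh1 (1.33) and the neutrophil gene S100a9 (1.21) completed the 10 largest rises, with adjusted p between 1.71e-06 and 0.0217. The call of Folh1 ended without KO 1 (log2 change 1.31) and without WT 86 (1.30).

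In all, 1013 of 17038 genes passed the test, 681 higher and 332 lower in the KO-labelled libraries. Changes of at least 1 on the log2 scale were more often falls, with 109 lower and 22 higher. In 1185 genes all KO-labelled libraries lay above all WT libraries and in 367 genes below, together 9.11% of those tested, where chance gives 0.79% on average. These counts are of the deposited values, without scaling between libraries. The median log2 change of all tested genes was 0.089, and the calls higher depended on scaling. Median-ratio scaling called 103 genes higher and 417 lower, quantile normalization 149 and 392, and protein-coding genes rescaled to their own reads, an alternative chosen after seeing the data, 493 and 394. The 681 became 194 without KO 1, 350 without KO 7, 241 without KO 8, 298 without KO 17, 382 without WT 9, 340 without WT 19, 223 without WT 86 and 250 without WT 89, and the 332 became 206 without KO 1.

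**Figure D2:**
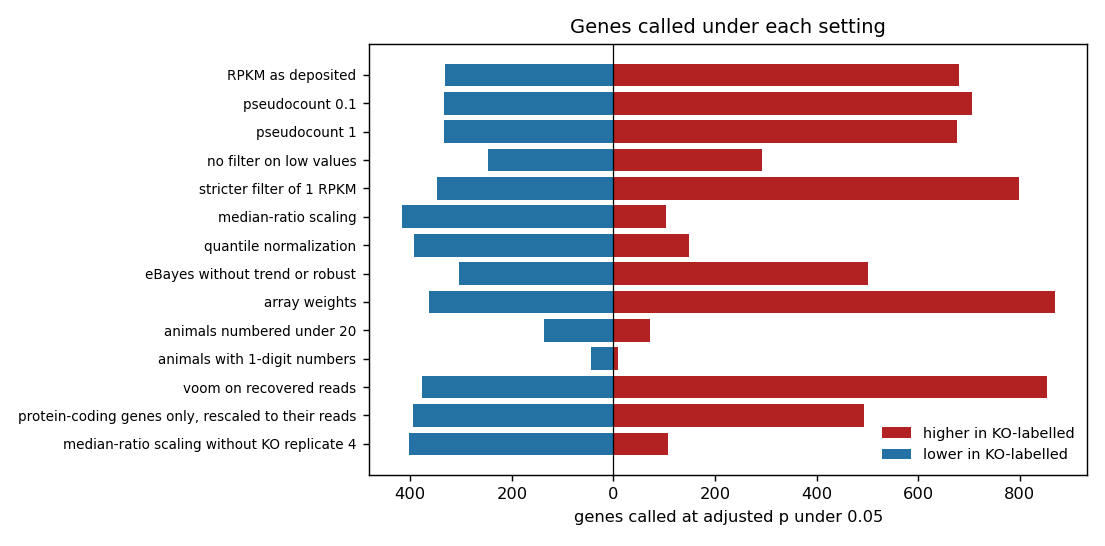
Number of genes called at an adjusted p under 0.05 (x axis) under each setting (y axis), with genes higher in the KO-labelled libraries to the right in red and genes lower to the left in blue. The deposited RPKM values gave 681 higher and 332 lower, and median-ratio scaling gave 103 higher and 417 lower.

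Adipocyte regulators and adipokines fell as a group. Of 24 tested members, 17 were lower and 1 higher (20 and 1 adjusted over the list alone), with a median log2 change of -0.96 (camera adjusted p = 1.88e-32; adjusted p = 0.0159 with an estimated correlation). Nnat, Adrb3, Retn and Cfd, which encodes adipsin, changed most, and Cfd went from 8815 to 1976 RPKM (fell by 2.15, SE 0.15). Adipoq (adiponectin) fell from 713 ± 99 to 307 ± 42 RPKM (log2 change -1.21, adjusted p = 5.20e-04). Pparg, the nuclear receptor that drives adipocyte differentiation, fell from 64.98 ± 9.96 to 29.7 ± 2.2 RPKM (log2 change -1.11, adjusted p = 2.60e-04). These 2 genes were chosen after their values were seen. In this list 15 of the 17 lower calls and 0 of the 1 higher were kept throughout, that is in each run that left out 1 library and under both scalings.

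Targets of PPARg for lipid uptake and the droplet coat had 12 members lower and 2 higher of 24 (16 and 3 adjusted over the list alone; camera adjusted p = 1.56e-18, adjusted p = 0.0159 with an estimated correlation). Besides Pck1, the largest falls were those of Cidec (log2 change -2.08), a lipid droplet fusion protein gene, Plin4 (-1.52) and the hormone-sensitive lipase gene Lipe (-1.52). Lipolysis genes had 8 lower of 15 and none higher (10 adjusted over the list alone; camera adjusted p = 7.78e-17, adjusted p = 0.0365 with an estimated correlation). Among them were Adrb3, Lipe, Plin1 (-1.18) and Prkar2b (-1.14). All 8 lower calls of lipolysis genes were kept throughout, as were 10 of the 12 lower and 1 of the 2 higher calls of PPARg targets.

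De novo fatty acid synthesis genes had 11 lower and 1 higher of 21 (14 and 3 adjusted over the list alone; camera adjusted p = 1.55e-14). The call was lost at adjusted p = 0.0819 with an estimated correlation. Scd1 and Fasn led, followed by Acaca (acetyl-CoA carboxylase, log2 change -1.99) and Thrsp (-1.78), whose call ended without KO 1 (-1.68) and without KO 8 (-1.69). Triglyceride synthesis genes had 9 lower and 1 higher of 16 (10 and 2 adjusted over the list alone; camera adjusted p = 1.63e-09; adjusted p = 0.0819 with an estimated correlation). Pck1, Acsl1 (-1.43), Dgat2 (-1.41) and the phosphatidate phosphatase gene Lpin1 (-1.09) fell. Calls kept throughout were 9 of the 11 lower for fatty acid synthesis and 7 of the 9 lower for triglyceride synthesis, and neither higher call was kept. The lists of adipocyte regulators, PPARg targets, lipolysis, fatty acid synthesis and triglyceride synthesis share members, such as Pck1, Lipe and Adrb3. In these 5 lists 48 different genes were called lower.

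**Figure D3:**
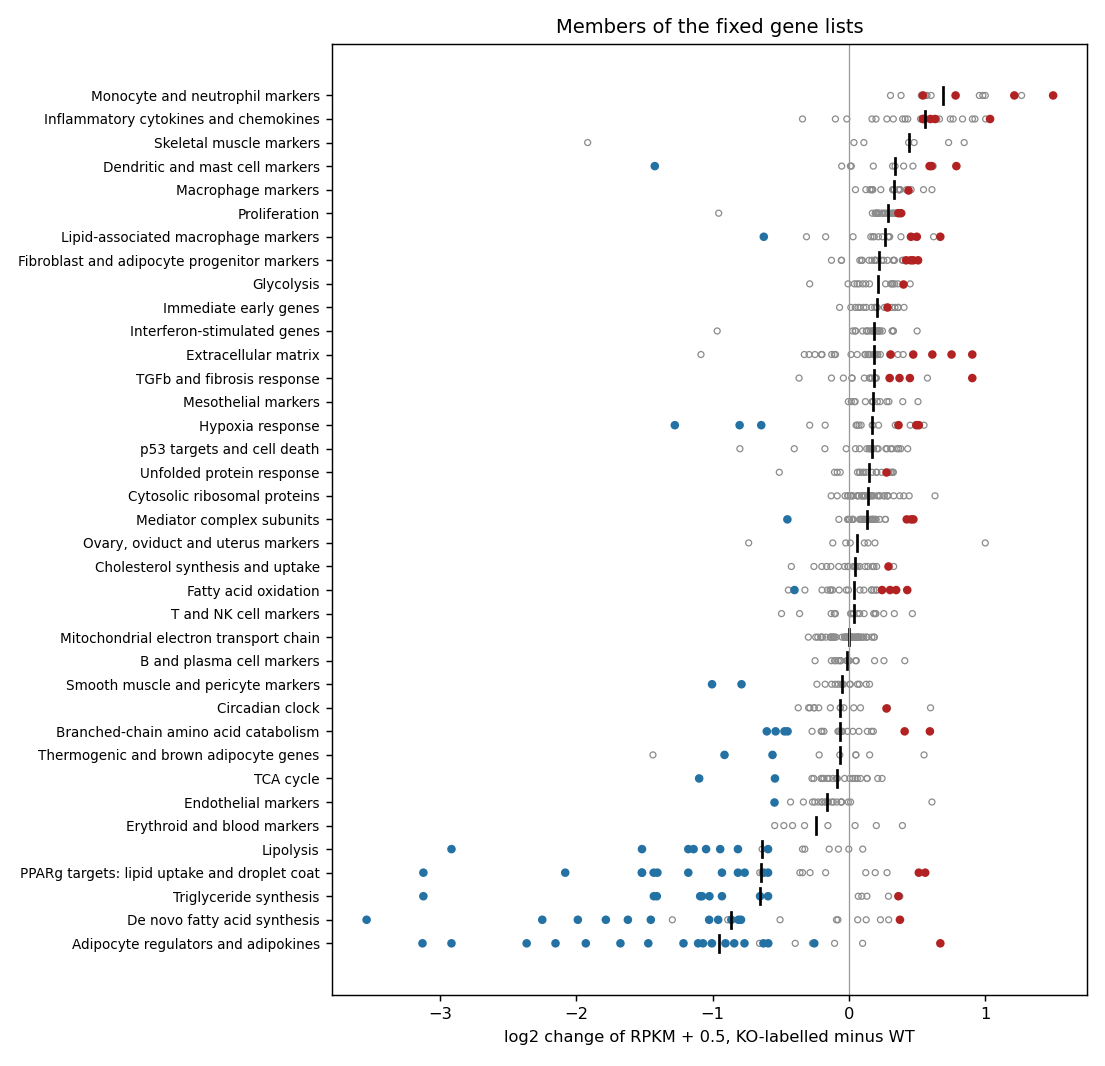
Log2 change of RPKM + 0.5, KO-labelled minus WT (x axis), of the tested members of 37 gene lists (y axis, ordered by median). Filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, and black lines are list medians, lowest for adipocyte regulators and adipokines at -0.96.

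Branched-chain amino acid catabolism had 4 lower and 2 higher of 21 (camera adjusted p = 0.00128; adjusted p = 0.483 with an estimated correlation), with Bcat2 at -0.60, Hibch at -0.54 and Acadsb at 0.59. Tricarboxylic acid cycle genes had 2 lower of 22, the pyruvate carboxylase gene Pcx (-1.10) and Pdha1 (-0.54) (camera adjusted p = 7.54e-04; adjusted p = 0.411 with an estimated correlation). Thermogenic genes had 2 lower of 9, among them the fatty acid receptor gene Ppara at -0.91 (camera adjusted p = 0.00706; adjusted p = 0.172 with an estimated correlation). This list was at adjusted p = 0.0663 without WT 86, 0.0757 in animals numbered under 20, 0.170 in animals with 1-digit numbers and 0.0840 with median-ratio scaling without KO 4, an alternative chosen after seeing the data. No member of the electron transport chain list passed, of 48 (camera adjusted p = 0.0241; adjusted p = 0.617 with an estimated correlation). That call ended without KO 7 (adjusted p = 0.0527), KO 8 (0.133) and WT 9 (0.346), and with no filter on low values (0.0826). Fatty acid oxidation had 4 higher and 1 lower of 22 (camera adjusted p = 0.696), with Cpt1a, the carnitine palmitoyltransferase gene, at 0.43 (adjusted p = 0.00124). Counts adjusted over the list alone were 4 lower and 2 higher for branched-chain amino acid catabolism, 3 and 2 for the tricarboxylic acid cycle, 2 and 0 for thermogenic genes, and 3 and 6 for fatty acid oxidation. Calls kept throughout were 2 of 4 lower and 1 of 2 higher for branched-chain amino acid catabolism, 2 of 2 lower for the tricarboxylic acid cycle, 1 of 2 lower for thermogenic genes, and 1 of 4 higher and 0 of 1 lower for fatty acid oxidation. By fry, which tests a list against no change, adjusted p was 0.441 for branched-chain amino acid catabolism, 0.265 for the tricarboxylic acid cycle, 0.0952 for thermogenic genes and 0.990 for the electron transport chain.

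Markers of monocytes and neutrophils were higher as a list (camera adjusted p = 2.08e-05; adjusted p = 0.172 with an estimated correlation). Of 14 members 4 were higher, and 11 adjusted over the list alone. S100a9 rose from 110 ± 27 to 257 ± 64 RPKM, and the chemokine receptor gene Ccr2 rose by 0.54 on the log2 scale. Inflammatory cytokines and chemokines had 5 higher of 28 (11 adjusted over the list alone; camera adjusted p = 1.90e-04; adjusted p = 0.411 with an estimated correlation), with the lipocalin gene Lcn2 at 1.03, a call that ended without KO 1 (0.98), and the adhesion molecule gene Vcam1 at 0.60. Macrophage markers had 1 higher of 22, the integrin gene Itgam at 0.43, and 11 adjusted over the list alone (camera adjusted p = 2.49e-04; adjusted p = 0.405 with an estimated correlation). The call of Itgam ended without KO 1, KO 7, KO 8, WT 9, WT 86 or WT 89, at log2 changes of 0.39 to 0.44. Proliferation genes had 2 higher of 28, the topoisomerase gene Top2a at 0.36 and Plk1 at 0.38, and 20 adjusted over the list alone (camera adjusted p = 3.02e-06; adjusted p = 0.274 with an estimated correlation). Calls kept throughout were 2 of 4 for monocytes and neutrophils, those of S100a9 and Ccr2, 0 of 5 for inflammatory genes, 0 of 1 for macrophages and 0 of 2 for proliferation. Median-ratio scaling ended the calls of Vcam1, Itgam, Top2a and Plk1. Adjusted p by fry was 0.00209 for monocytes and neutrophils, 0.02005 for inflammatory genes, 0.0125 for macrophages and 0.00351 for proliferation. Fry does not compare a list with other genes, so the median rise of 0.089 over all tested genes enters it.

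Fibroblast and adipocyte progenitor markers had 4 higher of 24 (9 adjusted over the list alone; camera adjusted p = 0.00617; adjusted p = 0.172 with an estimated correlation). Median-ratio scaling and quantile normalization each ended all 4 calls, those of Cd24a, Lum, Clec11a and Cd55. Leaving out 1 library ended them in 8, 8, 7 and 4 of 10 runs, that of Cd55 without KO 1, KO 17, WT 86 or WT 89. Endothelial markers had 1 lower of 20, Kdr at -0.55 (1 adjusted over the list alone; camera adjusted p = 2.08e-05; adjusted p = 0.283 with an estimated correlation), a call that ended without any 1 library other than KO 8, at log2 changes of -0.58 to -0.49. Smooth muscle and pericyte markers had 2 lower of 16, Mcam (-1.01) and Cspg4 (-0.79), the same number adjusted over the list alone (camera adjusted p = 8.39e-04; adjusted p = 0.405 with an estimated correlation). Extracellular matrix genes had 5 higher of 34 (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.208), with Col12a1 at 0.61, the 1 call of the 5 that was kept throughout. Both calls of smooth muscle and pericyte markers were kept throughout. By fry, adjusted p was 5.43e-04 for fibroblast and adipocyte progenitor markers and 0.0952 for extracellular matrix genes. It was 0.199 for endothelial markers and 0.234 for smooth muscle and pericyte markers.

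Dendritic and mast cell markers had 3 higher and 1 lower of 13 (7 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.061). The mast cell protease genes Cpa3 and Cma1 rose by 0.79 and 0.61 on the log2 scale, and the 1 fall was that of the receptor gene Kit, by 1.43. Lipid-associated macrophage markers had 3 higher and 1 lower of 18 (4 and 2 adjusted over the list alone; camera adjusted p = 0.154), with Spp1 (osteopontin) at 0.67 and Lpl at -0.63. Hypoxia response genes had 3 higher and 3 lower of 19 (6 and 3 adjusted over the list alone; camera adjusted p = 0.844), with Pfkfb3 at -1.28 and Bnip3 at -0.80. Mediator subunits had 3 higher and 1 lower of 31 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0545), with Med31 at 0.47. Calls kept throughout were 2 of 3 higher and 1 of 1 lower for dendritic and mast cells, 1 of 3 higher and 1 of 1 lower for lipid-associated macrophages, 1 of 3 higher and 2 of 3 lower for hypoxia, and 1 of 3 higher and 0 of 1 lower for Mediator subunits. Fry, into which the rise of all genes enters, gave an adjusted p of 2.20e-05 for Mediator subunits and 2.89e-04 for dendritic and mast cells. It gave 0.0741 for lipid-associated macrophages and 0.322 for hypoxia.

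The remaining lists were not called by camera. TGFb and fibrosis response had 4 higher of 18 (adjusted p = 0.0664), glycolysis 1 of 16 (0.0673), cholesterol synthesis 1 of 21 (0.366), the unfolded protein response 1 of 20 (0.191), immediate early genes 1 of 20 (0.363) and the circadian clock 1 of 15 (0.0899). None of these calls was kept throughout, and both scalings ended each of the 4 calls of the TGFb list, those of Timp1, Tgfb3, Tgfbi and Skil. No member passed among 24 interferon-stimulated genes (0.239), 23 p53 targets (0.200), 13 mesothelial markers (0.0949), 38 ribosomal proteins (0.240), 19 T and NK cell markers (0.405), 16 B and plasma cell markers (0.154), 8 erythroid markers (0.154), 7 skeletal muscle markers (0.607) and 8 ovary, oviduct and uterus markers (0.463). Adjusted over the list alone, TGFb had 8 higher and 1 lower, glycolysis 4 higher, cholesterol synthesis 1 higher and 1 lower, the circadian clock 2 higher and 1 lower, the unfolded protein response 6 higher, p53 targets 4 higher and 2 lower, and mesothelial markers 3 higher. Mammary epithelial markers had 4 tested members, too few for camera, with no called gene and 1 higher and 1 lower adjusted over the list alone. Fry, with the rise of all genes again included, gave an adjusted p of 3.87e-04 for the TGFb list and 0.00931 for the unfolded protein response. It gave 0.00938 for mesothelial markers, 0.0107 for p53 targets and 0.0440 for glycolysis. For the other lists of this paragraph that were tested, it gave 0.181 or more. The immunoglobulin gene Igkc was at 2162 RPKM in the KO-labelled libraries and 2170 RPKM in WT. Median, mean and test differed in sign for the electron transport chain, fatty acid oxidation, cholesterol synthesis, T and NK cell, B and plasma cell, ovary, skeletal muscle and hypoxia lists.

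Camera called 16 lists, 5 higher and 11 lower, and 3 of the 16 held with an estimated correlation. The 5 lists higher became 16 with no filter on low values, where 10 were lower, 9 in animals with 1-digit numbers, 12 with fry, 8 without KO 8, 10 without KO 17, 8 without WT 19 and 8 without WT 86. At the preset correlation, 26 of 100 groupings of the same 10 libraries gave as many called lists, the real grouping included.

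Of 44475 transcripts tested, 41 were higher and 201 lower in the KO-labelled libraries. The lower transcripts belonged to 152 genes, of which 141 were also called lower as genes, and the higher ones to 40 genes, of which 28 were called higher as genes, with 0 in the opposite direction. The 41 became 17 without KO 1, 26 without KO 7, 20 without KO 8, 22 without WT 9, 24 without WT 19, 26 without WT 86 and 24 without WT 89, and the 201 became 116 without KO 1, 133 without KO 8, 125 without WT 9, 131 without WT 86 and 133 without WT 89.

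The first principal component of the tested genes held 21.4% of the variance and separated the groups, with the KO-labelled libraries between -26.4 and -9.04 and the WT libraries between 7.47 and 26.3. The second held 15.7% and was set by KO 4 at -40.4. Correlations of log2 values across genes ran from 0.955 to 0.971 within groups and from 0.952 to 0.967 between groups, and genes are not independent replicates.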

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

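Each value below lay far from the other 4 libraries of its group, by a gap above 0.71 of the group's range. Chance alone marks about 1 in 20 groups, and 16 of 296 groups of 5 were marked, so single marks are given as values only.

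Ucp1, the uncoupling protein of brown fat, was below the filter and stood out in both groups. WT 86 had 13.4 RPKM against 0.204 to 2.78 RPKM in the other WT libraries, and KO 7 had 5.70 RPKM against 0 to 0.0794 RPKM in the other KO-labelled libraries. Scd1 was at 3642 RPKM in WT 86 against 2024 to 2439 RPKM in the other WT libraries. Pck1 was at 33.1 RPKM in KO 7 against 20.1 to 23.5 RPKM in its group. C6 was at 15.5 RPKM in KO 8 against 18.8 to 19.99 RPKM, Kdr was at 18.1 RPKM in KO 8 against 10.7 to 12.5 RPKM, and Slc7a10 was at 8.48 RPKM in KO 8 against 11.6 to 12.3 RPKM.

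WT 2 was the highest WT library for Retnlg (9.27 RPKM against 2.64 to 3.75), Thy1 (17.1 RPKM against 14.0 to 14.3) and Cd55 (12.3 RPKM against 11.5 to 11.7). KO 1 was the highest of its group for Cpa3 (4.85 RPKM against 3.37 to 3.71) and Timp1 (150.5 RPKM against 90.0 to 104). Phlda3 was at 118 RPKM in WT 9 against 53.3 to 67.1 RPKM, and Tgfb3 at 12.4 RPKM in WT 86 against 9.59 to 10.2 RPKM.

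Gm26917 and Gm42418 took 5.28% of the reads of WT 89 against 0.824% to 1.66% in the other WT libraries, and 0.905% in KO 17 against 0.527% to 0.622% in the other KO-labelled libraries.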

How the results depend on the processing

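The tests with voom, with protein-coding genes and with median-ratio scaling without KO 4 were chosen only after the results were seen. Of 95 named genes called, 55 kept their call in each run that left out 1 library and under both scalings, 35 of 42 falls and 20 of 53 rises. Named genes were picked for large changes, some after their values were seen, so this share does not stand for all calls. Of all calls, 103 of 681 higher and 330 of 332 lower were kept with median-ratio scaling. Without KO 1, 183 of the higher and 203 of the lower calls were kept. Median-ratio scaling ended 31 named rises and 0 named falls. It shifts every gene of a library by one factor, which lowered the median log2 change from 0.089 to 0.009. Under each alternative 0 of the 1013 called genes were called in the opposite direction. The 5 lists of adipocyte regulators, PPARg targets, fatty acid synthesis, triglyceride synthesis and lipolysis kept their calls under each alternative except that an estimated correlation ended those of fatty acid and triglyceride synthesis. Voom on recovered reads called 854 genes higher and 377 lower. Without a filter 29359 genes were tested and fewer were called. For the values below the cause was not tested, also where fewer animals or more genes entered.

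Genes higher, 681, became 292 with no filter, 103 with median-ratio scaling, 149 with quantile normalization, 71 in animals numbered under 20, 8 in animals with 1-digit numbers and 107 with median-ratio scaling without KO 4. Genes lower, 332, became 137 and 44 in those 2 subsets of animals. The first subset was without WT 86 and WT 89, and the second also without KO 17 and WT 19. Leaving out 1 library gave 194 to 697 higher and 206 to 316 lower. Transcripts ranged from 17 to 55 higher and 116 to 176 lower. Lists higher, 5, became 16 with no filter, 9 in animals with 1-digit numbers, 0 with an estimated correlation and 12 with fry, and 5 to 10 with 1 library left out. Lists lower, 11, became 3 with an estimated correlation and 5 with fry.

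The Med19 difference of 0.0931 RPKM was -0.312 with median-ratio scaling, -0.143 and -0.621 in its transcripts, and -0.205 to 0.398 with 1 library left out, with exact permutation p between 0.286 and 0.968. Its log2 change, 0.02, was -0.0655 with median-ratio scaling, -0.046 with quantile normalization, -0.0629 under number 20, -0.1601 with 1-digit numbers, -0.0092 in protein-coding genes and -0.0373 to 0.0833 with 1 library left out.

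The other changes of sign were in genes and lists that were not called. With median-ratio scaling they were Cox8a -0.0816, Sc5d -0.0606, Igkc -0.0443, skeletal muscle 0.0559 and hypoxia -0.0324. With quantile normalization they were Sc5d -0.0607, Ighm 0.0385, skeletal muscle 0.0291 and hypoxia -0.039. Without a filter they were fatty acid oxidation -0.0243, skeletal muscle 0.2071 and hypoxia -0.0034. Under number 20 they were Aldoa 0.0042, Ighm 0.1745, fatty acid oxidation -0.0147, cholesterol 0.0253, skeletal muscle 0.2763 and ribosomal proteins 0.0116. With 1-digit numbers they were Cox8a -0.1096, Aldoa 0.0094, Sc5d -0.0936, Ighm 0.0074, Nr1d1 0.1552, fatty acid oxidation -0.026, interferon -0.0511, skeletal muscle 0.5308, hypoxia 0.0284 and ribosomal proteins 0.0116. With fry, fatty acid oxidation was 0.0183, cholesterol 0.0184, T and NK cells 0.0346, B cells 0.0085, ovary 0.0711, skeletal muscle 0.1023 and hypoxia 0.0374. In protein-coding genes Cox8a was -0.0208 and Sc5d -0.0008, and with median-ratio scaling without KO 4 Cox8a was -0.0265, Sc5d -0.074, Igkc -0.166, Star -0.0363, Rpl8 -0.131 and T and NK cells 0.0377. With 1 library left out the ranges were Cox8a -0.0752 to 0.0605, Igkc -0.1493 to 0.2662, Rpl8 -0.0441 to 0.2329, Aldoa -0.0522 to 0.0394, Ighm -0.1365 to 0.1995, Sc5d -0.1121 to 0.112, skeletal muscle -0.4255 to 0.4926, immediate early genes -0.0036 to 0.2187, fatty acid oxidation -0.0787 to -0.0148, cholesterol -0.0893 to 0.0033, hypoxia -0.0415 to -0.0032 and T and NK cells -0.08 to 0.0724. List values are the mean log2 change minus that of all genes, and for fry the mean log2 change alone; a list's direction is the one its test gave.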

Other observations

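The tests on scaling, on Adipoq, on other cell types and on Med19 were chosen only after the results they bear on were seen, and the counts of other groupings were planned before they were run. Several further genes, chosen after their values were seen, went with the 2 directions of the report. The amino acid transporter gene Slc7a10 fell from 50.9 ± 7.3 to 11.3 ± 1.6 RPKM (log2 change -2.13, adjusted p = 1.04e-05, n = 5 each), and the growth factor gene Nrg4 from 11.5 ± 2.2 to 3.13 ± 0.42 RPKM (-1.71). The apolipoprotein gene Apoc1 rose from 46.5 ± 8.5 to 96.3 ± 20.4 RPKM (1.04), the matrix gene Dpt from 88.4 ± 10.7 to 175.5 ± 28.1 RPKM (0.98) and the proteoglycan gene Srgn from 109 ± 16 to 195 ± 34 RPKM (0.83). S100a8, the partner of S100a9, was at 323 RPKM in the KO-labelled libraries and 127 RPKM in WT and did not pass (adjusted p = 0.0529). The immunoglobulin segment Igkv14-111 was at 61.1 ± 44.2 against 12.9 ± 7.3 RPKM (log2 change 2.08, adjusted p = 0.0329), a call that ended without KO 1, KO 4, KO 7, WT 9, WT 19, WT 86 or WT 89, at log2 changes of 1.73 to 2.15, and with median-ratio scaling.

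The labels name polyA RNA, yet Rpph1, Rn7sk and Rmrp, whose transcripts are not polyadenylated, took 1.80 ± 0.27% of reads in the KO-labelled libraries and 1.56 ± 0.14% in WT (exact permutation p = 0.103, adjusted p = 0.181 over 7 classes). Mitochondrial rRNA took 0.239% of the reads of KO 4 and 1.38% to 2.20% in the other 9 libraries. Gm26917 and Gm42418 took 0.641 ± 0.152% in the KO-labelled libraries and 1.99 ± 1.86% in WT (exact permutation p = 0.0159, adjusted p = 0.111 over 7 classes).

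More genes were called higher than lower, 681 against 332. The 332 lower genes took 10.3 ± 1.28% of reads in WT and 4.18 ± 0.32% in the KO-labelled libraries, which by itself would raise all other genes by 0.095 on the log2 scale in RPKM. The median change of all tested genes was 0.089, so reads freed by the fall of abundant genes may account for the excess of small rises. The same shift does not account for the 103 genes that were still called higher after median-ratio scaling. Whether the total RNA per cell changed was not measured.

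The fall of adipocyte genes may reflect less RNA per adipocyte for selected genes or a lower adipocyte share of the tissue. Of 87 other tested members of the 5 adipocyte lists, called or not, 9 fell beyond Adipoq with the groups separated (Scd1, Nnat, Pck1, Adrb3, Retn, Fasn, Cfd, Cidec and Rbp4). In the same ratio 40 lay above Adipoq with the groups separated, and 38 did neither. The exact permutation p for the 9 was 0.00794, the smallest this design allows. Adipoq was taken as the reference after the changes were seen, so this p tests only whether ratios to Adipoq differed between the groups. If Adipoq falls in step with the adipocyte share, the 9 falls beyond it argue against a lower share as the whole cause. Markers of 6 other cell types, myeloid cells left out, moved apart (exact permutation p = 0.0317 for the spread of their mean log2 changes). Mean changes were 0.23 for fibroblast and progenitor, 0.19 for mesothelial, 0.035 for T and NK cell and 0.008 for B and plasma cell markers. Smooth muscle and pericyte markers (median -0.053) and endothelial markers each had a mean of -0.14. Monocyte and neutrophil markers were at 0.80 and macrophage markers at 0.31. The spread cannot decide on the adipocyte share, since other cell types can change among themselves whether or not that share fell. A lower share as part of the fall stays open, as does an effect of the genotype or of tamoxifen, which the labels do not state for the controls.

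No difference in Med19 RNA was detected, although the labels give an adipocyte knockout. An exchange of single libraries between the groups is argued against only if the first principal component follows the genotype, which the Med19 level did not check. On that component 0 of 10 libraries lay on the other group's side. An exchange of whole groups is not tested by this. Med19 RNA from cells other than adipocytes could hide a fall within adipocytes, and the lower bound of the ratio, 0.862, limits only the fall in the whole tissue, with the upper bound at 1.19. RNA of isolated adipocytes, or reads over the deleted exons, were not analysed here, so this explanation stays open.

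Other groupings of the 10 libraries were fitted for 100 of the 126 possible splits into 5 and 5, the real one included. The real split called 1013 genes and the highest other split 8, so 1 of 100 splits gave as many. With the real split included, 1 of 100 is the fewest this count can give. Every other split mixed libraries of both groups, and other differences that run with the labels are not tested by this. For transcripts the real split gave 242 and the highest other 78, again 1 of 100. For lists at the preset correlation the real split called 16, the highest other 23, and 26 of 100 splits gave as many, so chance cannot be excluded for that count. With an estimated correlation the real split called 3 lists and the highest other 0, so 1 of 100 splits gave as many. The lists of adipocyte regulators, PPARg targets, fatty acid synthesis, triglyceride synthesis and lipolysis had their smallest camera p in 1 of 100 splits, the real one. Among the other 11 called lists, thermogenic genes and monocyte and neutrophil markers had a p as small in 5 of 100 splits each, proliferation in 7, macrophage, fibroblast and endothelial markers in 13 each, smooth muscle markers in 19, the tricarboxylic acid cycle in 20, branched-chain amino acid catabolism in 25, inflammatory cytokines in 31 and the electron transport chain in 44. Of the lists not called, Mediator subunits had a p as small in 4 of 100 splits, the fewest, and dendritic and mast cell markers in 9.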
